A study of Antirrhinum majus with 21 samples.

How the data were processed

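Corolla RNA of *Antirrhinum majus* (snapdragon) flower buds was sequenced as 50 bp single-end reads from TruSeq libraries, 1 library per plant, in 21 plants of 7 genotype combinations with 3 plants each. Per the labels, the buds were 5 to 10 mm long, at stage 12 to 13, and the plants grew on outside benches. Each label gives 1 allele at each of the linked flower colour loci ROSEA (ROS) and ELUTA (EL) and no zygosity.

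Per the submitters' processing notes, cutadapt 1.16, Salmon 0.9.1 and DESeq2 were used, with no role or order given. The authors deposited 1 Salmon table per library, with an estimated count (expected count) for each of 51926 transcripts, not normalised. The same deposited tables give TPM, which Salmon scales to the same total in each library; TPM was not used in any test. A deposited placement file puts the transcripts on the scaffolds of the JICv1 assembly, per its file name, and gives an exonerate alignment score per placement; the authors' score was used only to choose among placements. Whether counting used strand, and the Salmon settings, were not given in the sources used here.

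Transcripts were summed to 37234 genes by the shared part of their IDs, and the sums were rounded to whole numbers. Each gene took the placement with the highest score, and ties went to the first sequence by name. Of the genes tested, 237 had placements on more than 1 sequence. Coordinates are 1-based on JICv1. A sequence of that assembly is named ros_assembly, after the ROS locus; 125 genes were placed on it and 80 of them were tested. The files do not pair IDs with gene names, so genes are given by ID, and the pigment gene lists fixed in advance could not be matched and were not run.

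The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with limma 3.58.1, TMM normalisation and 1 mean per genotype, fitted to all 21 libraries together. Genes with at least 0.5 CPM in at least 3 libraries were kept, 24674 in all. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were computed as the absolute fold change divided by the square root of F. The biological coefficient of variation was 0.400. Library totals ran from 8926585 to 41860890 estimated reads. Where all libraries of a group were at 0, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with a 95% counting interval. Floors and intervals cover counting error only, and a fitted log2 fold change of such a gene depends on the prior count and is no bound.

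The 13 comparisons were 9 pairs of genotypes, magenta against white, eluta against magenta, and 2 interactions. Calls shared between independent pairs were counted per direction with a one-sided Fisher exact test. Since the sequences have no chromosome names, calls were counted by scaffold, with a two-sided Fisher exact test on scaffolds with at least 100 tested genes. Sequences with at least 10 tested genes, ros_assembly among them, were added after the data were examined. The largest count of calls in any 1 Mb window was set against 10000 random draws. The genes named were, per comparison, up to 2 with the largest rise and 2 with the largest fall among called genes with a mean of at least 1 CPM in the higher group and no overlap between the libraries of the groups. Genes named outside that rule are said to be chosen after their values were seen. The comparisons, the tests and this rule were fixed before the data were examined.

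The alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, the library number series or the plant family as a term, only the groups compared, and each replicate left out in turn. Plant family was fitted only for comparisons among rosdor_eldor, ROSpse_elpse, ROSpse_ELstr and rosstr_ELstr. The other genotypes came from families that held no other genotype, so there family and genotype could not be separated. For the windows, 0.5 Mb and an adjusted p under 0.01 were tried. A fit to the middle library number series alone was added after the data were examined. That series is read from the library numbers: 5 libraries lie below 3000, 13 in the middle, and 3 above 8000. The procedure was tested on simulated counts for ROSpse_ELstr against ROSpse_elpse. There edgeR recovered 43% of 100 genes changed 2-fold and 80% of 100 changed 4-fold, and called 8 unchanged genes among 24302 tested. DESeq2 recovered 58% and 92% and called 46 unchanged genes, among 24674. The changes were placed only among the more highly expressed genes, so recovery over all tested genes may be lower. Apart from them, counts were drawn from a common mean per gene, with no structure of family or library series.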

Results

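Corolla transcripts were measured in 21 snapdragon plants that carried 7 combinations of alleles at ROS and EL. ROS and EL are linked loci that set how much magenta anthocyanin pigment the corolla makes and where. The magenta genotypes were ROSji7_elji7 (alleles of the laboratory line JI7) and ROSpse_elpse (alleles of the wild magenta *pseudomajus*). The eluta genotypes, ROSji7_ELstr and ROSpse_ELstr, joined such a ROS allele to the EL allele of the wild yellow *striatum*. The white genotypes were rosdor_eldor and rosstr_ELstr. The pale genotype rosrec_elpse carried a recombinant ROS allele, of *striatum* upstream and *pseudomajus* downstream. Each had 3 plants, and the labels do not pair plants across genotypes.

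Totals ran from 8926585 estimated reads in rosdor_eldor replicate 1 to 41860890 in rosstr_ELstr replicate 1. Over the 21 pairs of replicates, Spearman's rho across genes was 0.910 to 0.981. Counts of replicates differed by far more than sampling noise, with a chi-square per degree of freedom of 30.9 to 163, so no library was counted as a copy. The first principal component held 19.1% of the variance and the second 12.8%. On the first, the 5 libraries of the low number series lay between 9.57 and 111, those of the middle series between -78.1 and 51.1, and the 3 of the high series between -42.8 and -11.7. All 3 rosrec_elpse libraries were of the low or high series. Except for rosdor_eldor, whose 3 plants came from families A181, A174 and A182, each genotype came from 1 family, so genotype and family were largely joined.

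**Figure D1:**
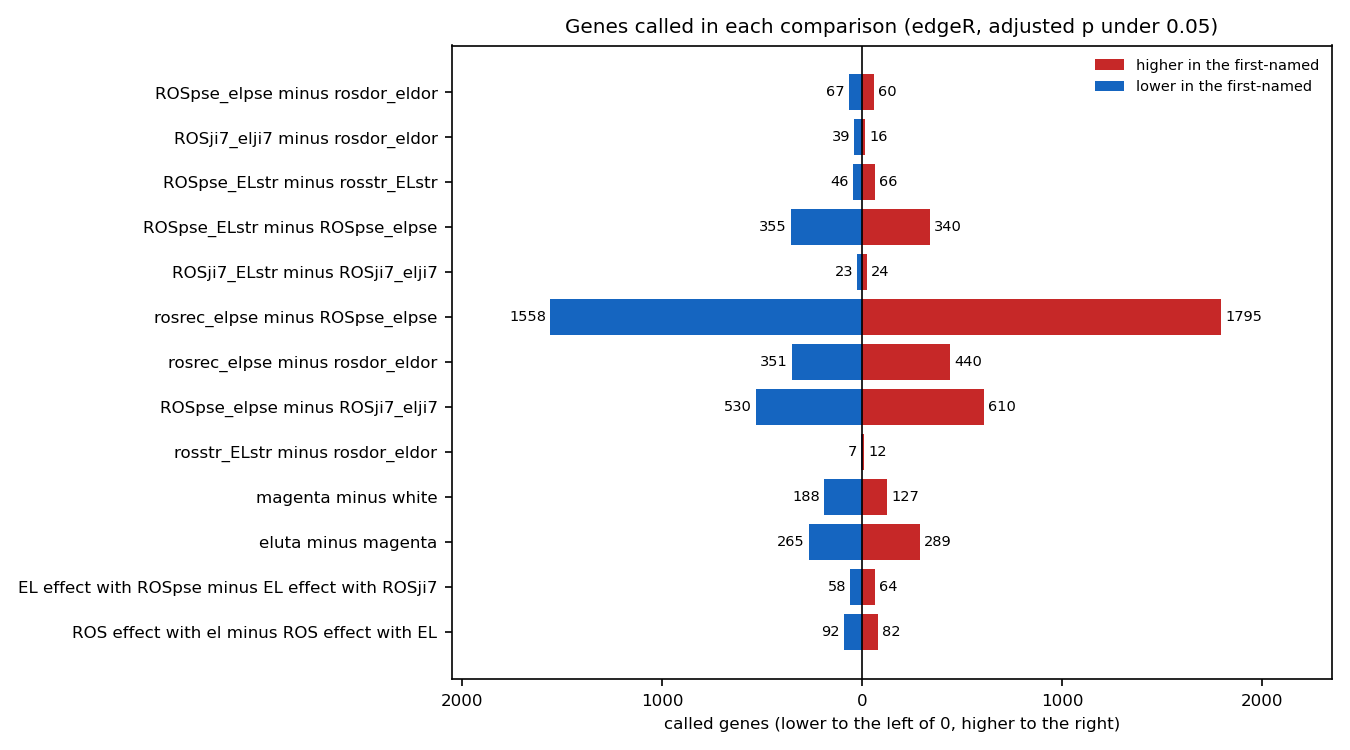
Bars give the number of genes called higher (right of 0) or lower (left of 0) in the first-named genotype or group of each comparison, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The counts run from 19 between the white genotypes to 3353 between rosrec_elpse and ROSpse_elpse.

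The first question was which genes differ with a dominant ROS allele. AnMG0000144700, placed on ros_assembly at 541660 to 544383 on the plus strand, was the gene called in all 3 ROS comparisons. Its mean was 27.8 ± 19.0 CPM in ROSpse_elpse, 27.6 ± 25.3 in ROSji7_elji7 and 40.4 ± 16.0 in ROSpse_ELstr, against 0.896 ± 0.817 in rosdor_eldor and 2.08 ± 0.557 in rosstr_ELstr (SD, n = 3). It was 64.7 ± 11.2 CPM in ROSji7_ELstr and 24.6 ± 5.66 in rosrec_elpse. The log2 fold changes were 4.96 for ROSpse_elpse and 4.95 for ROSji7_elji7 against rosdor_eldor (edgeR adjusted p 0.0194 and 0.0201) and 4.27 for ROSpse_ELstr against rosstr_ELstr (edgeR adjusted p 0.0291). The gene was chosen after its values were seen, and the ROSpse_elpse and ROSji7_elji7 comparisons share the rosdor_eldor libraries.

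The calls of AnMG0000144700 depended on single libraries. For ROSpse_elpse, the edgeR adjusted p was 0.0683 without rosdor_eldor replicate 3, 0.0549 without ROSpse_elpse replicate 1 and 0.0512 without its replicate 2, in a range over all alternatives of 3.56e-08 to 0.259. For ROSji7_elji7, the edgeR adjusted p was 0.0745 without rosdor_eldor replicate 1 and 0.0694 without replicate 3, in a range of 2.05e-08 to 0.769. In ROSpse_ELstr against rosstr_ELstr the call ended without any of the 6 libraries, at an edgeR adjusted p of 0.0645 to 0.127, with log2 fold changes of 3.87 to 4.52. With plant family as a term that fold change was 0.00 and the edgeR adjusted p 1.0, a fit that rests on 1 rosdor_eldor plant per family.

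**Figure D2:**
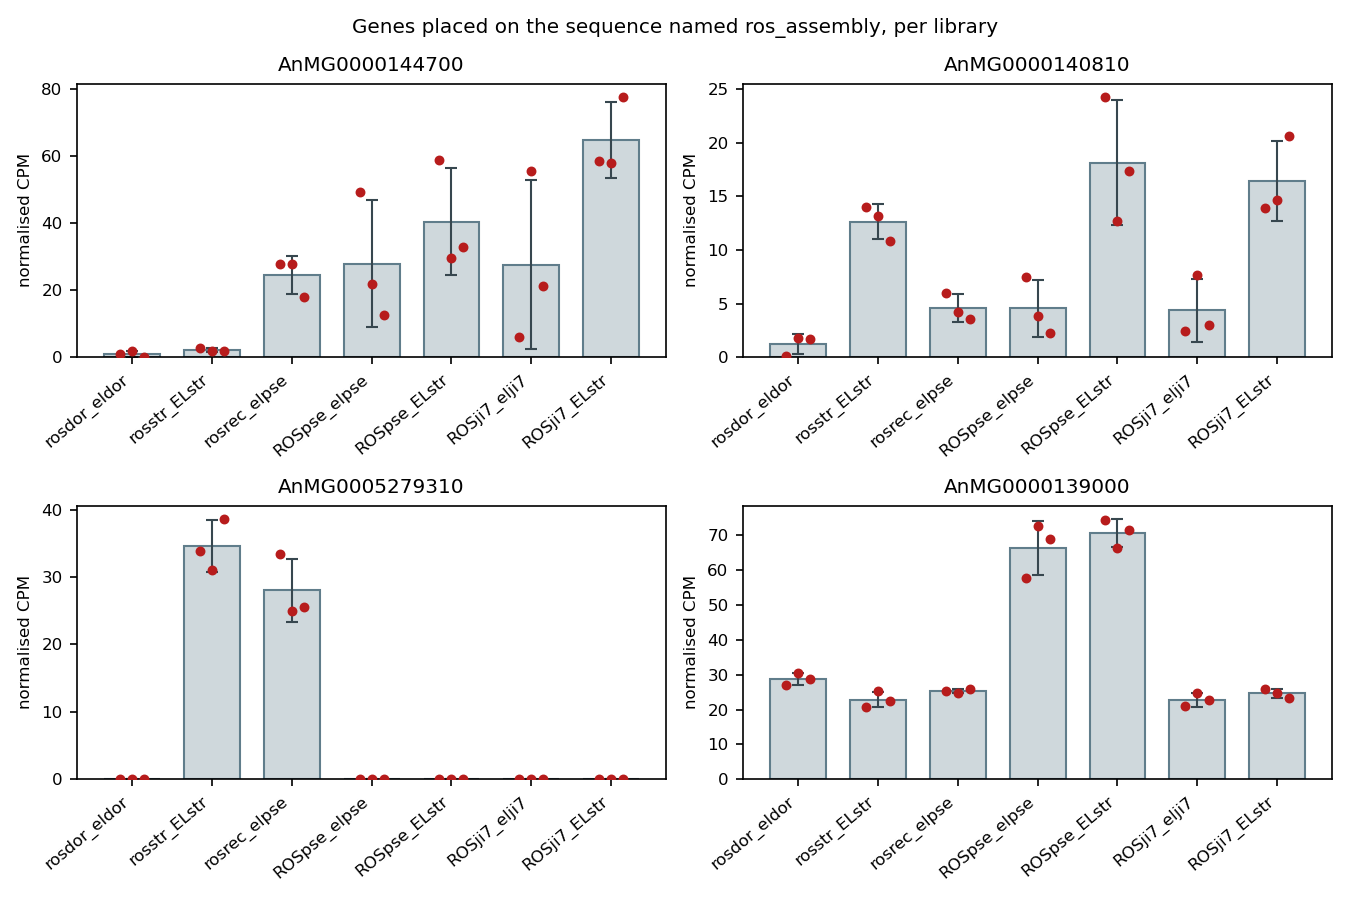
Normalised CPM per library of 4 genes on ros_assembly; bars are means, error bars are 1 SD and points are the 3 plants of each genotype. AnMG0000144700 averaged 0.896 and 2.08 CPM in the white genotypes and 24.6 or more in the others.

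Between ROSpse_elpse and rosdor_eldor, 60 genes were higher and 67 lower. AnMG0000146600 (ros_assembly 624419 to 626533, minus strand) was at 0.0868 ± 0.0875 CPM in ROSpse_elpse and 29.8 ± 19.1 in rosdor_eldor (SD, n = 3), a log2 fold change of -8.46 ± 1.05 (SE; edgeR adjusted p 0.00228; 0.0528 in the fit of these groups alone, in a range over alternatives of 1.10e-15 to 0.0528). AnMG0006039410 (scaffold454 635871 to 636562) was at 1.96 ± 0.304 CPM against 0, at least 47.9-fold higher; it overlaps another gene on the same strand. Its edgeR adjusted p of 0.0263 became 0.0924 without rosdor_eldor replicate 2 and 0.110 without replicate 3, in a range over alternatives of 0.00344 to 0.232. Without any ROSpse_elpse replicate it was under the low-count filter and not tested. The count of 127 was 19 without rosdor_eldor replicate 2, 24 without its replicate 3, and 26, 13 and 59 without ROSpse_elpse replicates 1, 2 and 3. It was 33 in the middle library series alone and 34 with plant family as a term, 5 of them among the 127.

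Between ROSji7_elji7 and rosdor_eldor, 16 genes were higher and 39 lower. AnMG0001181400 (scaffold1539 41707 to 44231) was at 0 in ROSji7_elji7 and 9.26 ± 2.04 CPM in rosdor_eldor (SD, n = 3), at least 228-fold lower (edgeR adjusted p 1.32e-05). AnMG0000159200 (scaffold1195 273970 to 274999) was at 4.74 ± 1.89 CPM against 0, at least 114-fold higher. Its edgeR adjusted p of 0.00995 became 0.0676 without rosdor_eldor replicate 3, in a range over alternatives of 7.37e-08 to 0.119. The balance of directions rested on single libraries, with 18 higher and 13 lower without ROSji7_elji7 replicate 1, 97 and 58 without its replicate 2, and 58 and 23 without its replicate 3. The count of 55 was 31, 155 and 81 in these, and 18 without rosdor_eldor replicate 3. It was 44 in the middle library series.

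With a dominant EL allele in both, ROSpse_ELstr had 66 genes higher and 46 lower than rosstr_ELstr. AnMG0005279310 (ros_assembly 121686 to 123759) was at 0 in ROSpse_ELstr and 34.6 ± 3.86 CPM in rosstr_ELstr (SD, n = 3), at least 813-fold lower (edgeR adjusted p 1.03e-05; 0.216 with plant family as a term, in a range over alternatives of 1.38e-19 to 0.216). AnMG0006203300 was at 30.1 ± 15.9 against 0.150 ± 0.259 CPM, AnMG0006021300 at 9.68 ± 3.25 against 0.123 ± 0.109, and AnMG0607978800 at 0.0243 ± 0.0421 against 2.34 ± 1.14. Their calls (edgeR adjusted p 0.0340, 0.0435 and 0.0463) ended without any of the 6 libraries, except that AnMG0006203300 kept its call without rosstr_ELstr replicate 3. The count of 112 was 66, 21 and 5 without ROSpse_ELstr replicates 1, 2 and 3, and 8 and 15 without rosstr_ELstr replicates 1 and 2. It was 13 in the middle library series and 7 with plant family as a term, 2 of them among the 112. Of the genes called in ROSji7_elji7 against rosdor_eldor, which shares no library with it, 1 was called in the same direction, AnMG0000144700. Independent lists would share 0.0428 higher genes, and the one-sided Fisher exact p was 0.0420, or 0.0560 after Benjamini-Hochberg adjustment over 4 tests. The count of 1 was 3 without rosdor_eldor replicate 2. It was 0 without rosdor_eldor replicate 1 or 3, any ROSpse_ELstr replicate or any rosstr_ELstr replicate.

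Pooled by colour, the magenta genotypes had 127 genes higher and 188 lower than the white ones. AnMG0000144700 was among those higher, with a log2 fold change of 4.34 ± 0.58 (SE; edgeR adjusted p 0.00157), and stayed called in the 18 alternatives run, at an adjusted p of 1.03e-13 to 0.0492 (edgeR or DESeq2). Plant family as a term was not among the 18, since it could not be fitted to this contrast. With that term AnMG0000144700 was not called in ROSpse_elpse against rosdor_eldor or ROSpse_ELstr against rosstr_ELstr, at log2 fold changes of 4.97 and 0.00. AnMG0002422900 was at 7.53 ± 3.81 against 0.0116 ± 0.0285 CPM and AnMG0004076700 at 13.3 ± 6.55 against 0.167 ± 0.114 (edgeR adjusted p 0.0374 and 0.0300). The call of AnMG0002422900 ended without each library but ROSji7_elji7 replicate 1. That of AnMG0004076700 ended without rosdor_eldor replicate 2 or 3, ROSpse_elpse replicate 2 or 3 or any rosstr_ELstr replicate. AnMG0000433100 (scaffold460 480409 to 480873) was lower, at 0.277 ± 0.314 CPM in 6 magenta and 1.19 ± 0.391 in 6 white plants (SD). Its edgeR adjusted p of 0.0188 became 0.0502 without rosdor_eldor replicate 3 and 0.0550 without ROSpse_elpse replicate 2, in a range over alternatives of 1.27e-05 to 0.0550. The count of 315 was 180 without ROSji7_elji7 replicate 1, 84 without rosdor_eldor replicate 3, 97 and 146 without ROSpse_elpse replicates 2 and 3, and 138 without rosstr_ELstr replicate 1. In the middle library series it was 227.

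The next question was what the *striatum* EL allele changes. With ROSpse, 340 genes were higher and 355 lower in ROSpse_ELstr than in ROSpse_elpse. AnMG0907197600 (scaffold527 240073 to 240471) was at 10.1 ± 2.69 CPM against 0 (SD, n = 3), at least 273-fold higher (edgeR adjusted p 0.0220). AnMG0000590910 (scaffold874 53242 to 65970), which overlaps 2 genes on the same strand, was at 0 against 5.06 ± 0.863 CPM, at least 115-fold lower (edgeR adjusted p 0.0198). AnMG0907197600 lost its call without any ROSpse_elpse replicate and without ROSpse_ELstr replicates 2 and 3, at an edgeR adjusted p between 0.0384 and 0.0840 over the 6 leave-outs and 0.00908 to 1.0 over all alternatives. AnMG0000590910 lost it without ROSpse_elpse replicate 2 and ROSpse_ELstr replicates 2 and 3, at an edgeR adjusted p up to 0.0956, in a range over alternatives of 2.83e-06 to 0.558. With plant family as a term neither was called. The count of 695 was 460, 232 and 384 without ROSpse_elpse replicates 1, 2 and 3, and 162 and 398 without ROSpse_ELstr replicates 2 and 3. It was 178 in the middle library series and 13 with plant family as a term, 1 of them among the 695.

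With ROSji7, 24 genes were higher and 23 lower in ROSji7_ELstr than in ROSji7_elji7. AnMG0001020400 (scaffold1195 1110942 to 1113090), which overlaps another gene on the same strand, was at 37.5 ± 0.804 CPM against 0.116 ± 0.0711 (SD, n = 3), a log2 fold change of 8.29 ± 0.72 (SE; edgeR adjusted p 5.70e-05). It was called in all 12 alternatives run, among which plant family as a term could not be fitted. AnMG0000159200 was at 0.00930 ± 0.0161 against 4.74 ± 1.89 CPM. That is a ratio of 449 with a 95% counting interval from 80.1, and its edgeR adjusted p was 0.0105. Without ROSji7_ELstr replicate 1, 2 or 3 the call ended, at an edgeR adjusted p up to 0.108, in a range over alternatives of 4.31e-07 to 0.165. The even split of directions rested on single libraries, with 77 higher and 162 lower without ROSji7_elji7 replicate 2 and 24 and 102 without its replicate 3. The count of 47 was 24, 239 and 126 without ROSji7_elji7 replicates 1, 2 and 3, and 11, 15 and 16 without ROSji7_ELstr replicates 1, 2 and 3. It was 6 in the middle library series.

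The EL comparisons with ROSpse and ROSji7 share no library. They had 8 higher and 3 lower genes in common, where independent lists would share 0.331 each (one-sided Fisher exact p 7.27e-10 and 0.00422; 2.91e-09 and 0.00845 after Benjamini-Hochberg adjustment). Of the 11, 5 lay on scaffold1195, where both lists gather. Linked genes are not independent, as the Fisher test takes them to be, so these p are too small by an unknown amount. In rosstr_ELstr, which also carries ELstr, AnMG0000407600 and AnMG0000443700, both shared as lower, were at 38.7 and 18.7 CPM. Their eluta means were 1.89 to 2.87 CPM and their magenta means 20.6 to 43.3. AnMG0002964300 and AnMG0208343200, shared as higher, were at 725 and 65.6 CPM in rosstr_ELstr, against 1666 and 289 in ROSpse_ELstr. The others of the 11 lay nearer the eluta than the magenta means in rosstr_ELstr. A further 6 genes were called in opposite directions. Across all genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.0140 and a Spearman correlation of 0.0724. The count of 11 was 4, 20 and 17 without ROSji7_elji7 replicates 1, 2 and 3, and 4 without any ROSji7_ELstr replicate. In the middle library series it was 2. With plant family as a term, which rests on 1 rosdor_eldor plant per family, 1 of the 695 calls with ROSpse remained. That call was AnMG0001020400, 1 of the 11, which was called in all 13 alternatives run with ROSpse. Plant family could not be fitted with ROSji7, so under that term no more than this 1 of the 11 could still be shared.

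Pooled, the eluta genotypes had 289 genes higher and 265 lower than the magenta ones. AnMG0001020200 (scaffold1195 1109323 to 1110176) was at 3.73 ± 0.690 CPM in 6 eluta and 0.0546 ± 0.117 in 6 magenta plants (SD), a log2 fold change of 6.50 ± 0.79 (SE; edgeR adjusted p 0.00174). AnMG0001841800 (scaffold14 225526 to 226574) was at 7.34 ± 1.82 against 0.0896 ± 0.0710 CPM, a log2 fold change of 6.40 ± 0.51 (SE; edgeR adjusted p 8.11e-06). Both overlap another gene on the same strand. On ros_assembly, AnMG0000140810 (714682 to 716427, minus strand; chosen after its values were seen) was at 16.4 ± 3.69, 18.1 ± 5.84 and 12.7 ± 1.66 CPM in ROSji7_ELstr, ROSpse_ELstr and rosstr_ELstr (SD, n = 3). In the other genotypes its means were between 1.21 and 4.60 CPM. Its log2 fold change, eluta minus magenta, was 1.95 (edgeR adjusted p 0.0161; 0.0543 without ROSpse_elpse replicate 2, in a range over alternatives of 2.13e-05 to 0.0543). By edgeR it was called in neither EL pair, with an adjusted p of 0.0689 with ROSpse (0.00480 to 0.755 over alternatives) and 0.190 with ROSji7 (0.0235 to 0.407). With plant family as a term its log2 fold change with ROSpse turned to -1.77. The count of 554 was 257, 335 and 350 without ROSji7_ELstr replicates 1, 2 and 3, 245 without ROSpse_elpse replicate 2 and 241 without ROSpse_ELstr replicate 2. It was 152 in the middle library series.

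The recombinant genotype was compared with a magenta and a white one. rosrec_elpse had 1795 genes higher and 1558 lower than ROSpse_elpse. AnMG0005279310 was at 28.0 ± 4.69 CPM against 0 (SD, n = 3), at least 696-fold higher (edgeR adjusted p 7.58e-06). AnMG0000139000 (ros_assembly 295677 to 302251; chosen after its values were seen) was at 25.4 ± 0.535 against 66.4 ± 7.73 CPM, a log2 fold change of -1.39 (edgeR adjusted p 7.58e-06). AnMG0000144700 differed by less than the spread between replicates, with a log2 fold change of -0.18 (edgeR adjusted p 0.899). The count of 3353 was 1569 and 1930 without ROSpse_elpse replicates 2 and 3, and 2059 and 2060 without rosrec_elpse replicates 2 and 3. With no middle series library in rosrec_elpse, no within-series value could be had; with the series as a term the count was 2264.

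Against rosdor_eldor, rosrec_elpse had 440 genes higher and 351 lower. AnMG0000144700 was higher, with a log2 fold change of 4.78 (edgeR adjusted p 0.00819; 0.190 in the fit of these groups alone, in a range over alternatives of 4.64e-08 to 0.190). AnMG0005279310 was at 28.0 ± 4.69 against 0.0200 ± 0.0174 CPM (SD, n = 3), a ratio of 1008 with a 95% counting interval from 279 (edgeR adjusted p 4.00e-05). AnMG0000159200 was at 5.40 ± 1.49 CPM against 0, at least 137-fold higher (edgeR adjusted p 0.00399; 0.115 in the fit of these groups alone, in a range over alternatives of 2.12e-08 to 0.115). The count of 791 was 270 and 500 without rosdor_eldor replicates 1 and 3, and 367, 207 and 223 without rosrec_elpse replicates 1, 2 and 3. With the library series as a term it was 280, and in the fit of these groups alone 3.

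Genes of ros_assembly were then followed in rosrec_elpse. Of its tested genes, 13 differed between the mean of the ROSpse genotypes and rosstr_ELstr, at a p adjusted over the sequence by edgeR and Benjamini-Hochberg under 0.05. This list was drawn up after the data were examined. In 11 of them rosrec_elpse lay nearer rosstr_ELstr, and in 2, AnMG0000144700 and AnMG0000140910 (720073 to 726464), nearer ROSpse. In AnMG0000140910 rosrec_elpse lay below both, at a mean log2(CPM + 0.5) of 4.12 against 4.77 for ROSpse and 5.24 for rosstr_ELstr. In AnMG0000140900 and AnMG0000153000, counted as nearer rosstr_ELstr, it lay above both, at 5.01 against 4.33 and 4.77 and at 4.97 against 4.28 and 4.75. It also lay beyond rosstr_ELstr, by smaller parts of the difference, in AnMG0908756300, AnMG0000137900 and AnMG0000141300. AnMG0000144700 lay between them, at 90.9% of the way from rosstr_ELstr to ROSpse. The first 10 along the sequence, up to position 396940, all lay nearer rosstr_ELstr.

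**Figure D3:**
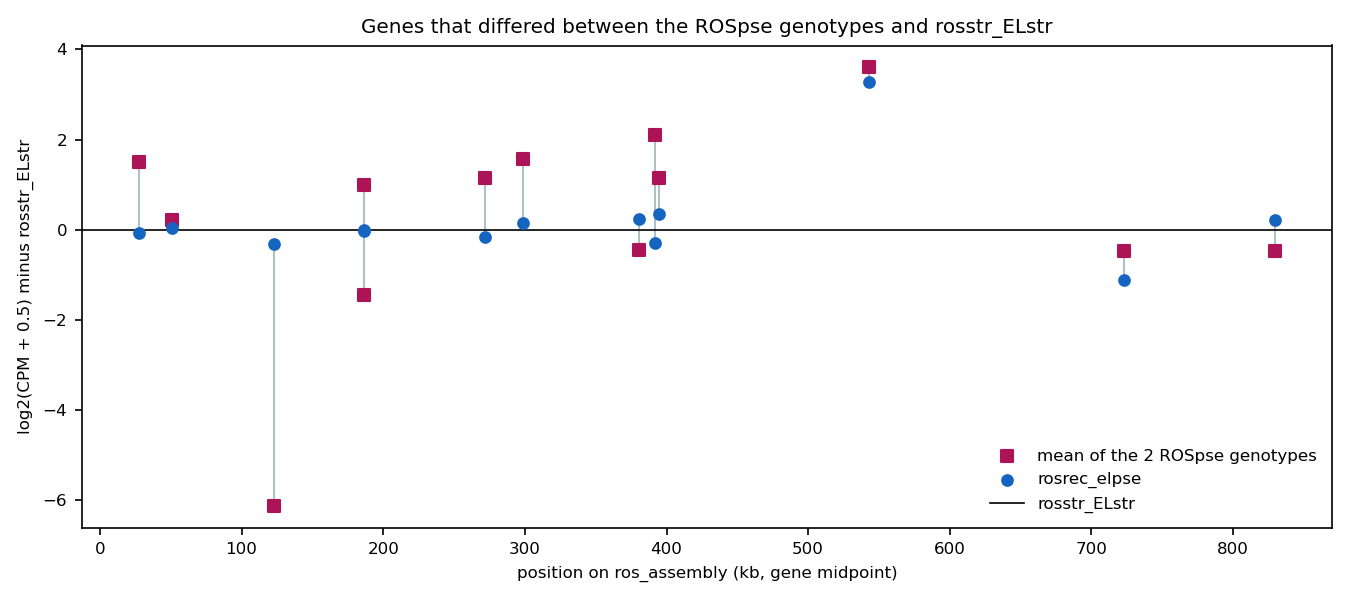
Each of 13 genes on ros_assembly is drawn at its midpoint (kb), with the difference in log2(CPM + 0.5) from rosstr_ELstr of rosrec_elpse (circles) and of the mean of the ROSpse genotypes (squares). In rosrec_elpse, 11 genes lie nearer the line at 0, which stands for rosstr_ELstr, and 2 nearer the squares.

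Between the magenta genotypes, ROSpse_elpse had 610 genes higher and 530 lower than ROSji7_elji7. AnMG0003632610 (scaffold272 183206 to 186721), which overlaps another gene on the same strand, was at 14.8 ± 4.61 CPM against 0 (SD, n = 3), at least 401-fold higher (edgeR adjusted p 0.0145). AnMG0000139000 was at 66.4 ± 7.73 against 22.8 ± 1.97 CPM, a log2 fold change of 1.54 (edgeR adjusted p 2.24e-06). Both were called in all 12 alternatives run, among which plant family as a term could not be fitted. The count of 1140 was 420 without ROSji7_elji7 replicate 1, and 567, 316 and 504 without ROSpse_elpse replicates 1, 2 and 3. It was 518 in the middle library series. The balance of directions also moved, with 214 higher and 61 lower in the fit of these groups alone. Without ROSji7_elji7 replicate 2 it was 563 higher and 735 lower.

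Between the white genotypes, rosstr_ELstr had 12 genes higher and 7 lower than rosdor_eldor. AnMG0005279310 was at 34.6 ± 3.86 against 0.0200 ± 0.0174 CPM (SD, n = 3; edgeR adjusted p 3.19e-05), and AnMG0000146610 (scaffold1195 208979 to 211732) at 7.75 ± 2.37 CPM against 0, at least 197-fold higher (edgeR adjusted p 9.64e-05). AnMG0000146600 was at 0.0188 ± 0.0171 against 29.8 ± 19.1 CPM (edgeR adjusted p 0.000560) and AnMG0000133410 (ros_assembly 393052 to 396940) at 2.39 ± 0.628 against 11.4 ± 2.87 CPM (edgeR adjusted p 0.00190). In the fit of these groups alone the edgeR adjusted p of AnMG0000146610, AnMG0000146600 and AnMG0000133410 was 0.264, 0.144 and 0.607, the highest of each gene's alternatives, whose lowest were 1.48e-11, 2.35e-13 and 1.71e-11. The majority turned to 12 higher and 40 lower without rosstr_ELstr replicate 3, and to 35 and 82 with DESeq2. The count of 19 was 10 and 29 without rosdor_eldor replicates 2 and 3, and 12 and 52 without rosstr_ELstr replicates 1 and 3. It was 8 in the middle library series and 9 with plant family as a term, 6 of them among the 19.

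The EL effect was set against itself between ROS alleles, and the ROS effect between EL alleles. The recessive allele changed too, elpse or elji7 in the first and rosdor or rosstr in the second. For 122 genes the EL effect differed between ROSpse and ROSji7, 64 with a larger value under ROSpse and 58 with a smaller one. That count was 76 without ROSji7_elji7 replicate 1, 57, 22 and 57 without ROSji7_ELstr replicates 1, 2 and 3, 67 and 44 without ROSpse_elpse replicates 1 and 2, and 27 and 69 without ROSpse_ELstr replicates 2 and 3. In the middle library series it was 45. The difference ROSpse_elpse minus rosdor_eldor departed from ROSpse_ELstr minus rosstr_ELstr with a larger value for 82 genes and a smaller one for 92.

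Both directions together, that count was 266 and 93 without rosdor_eldor replicates 1 and 2, 101 and 55 without ROSpse_elpse replicates 1 and 2, 56 and 89 without ROSpse_ELstr replicates 2 and 3, and 95 and 75 without rosstr_ELstr replicates 1 and 2. It was 22 in the middle library series and 10 with plant family as a term, none of them among the calls without that term.

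The naming rule gave further genes, most of whose edgeR calls rested on single libraries. Higher in ROSpse_elpse than in rosdor_eldor was AnMG0002921300, whose call ended without rosdor_eldor or ROSpse_elpse replicates 2 or 3. Lower was AnMG0003514000, whose call ended without rosdor_eldor replicate 2 or any ROSpse_elpse replicate. In ROSji7_elji7 against rosdor_eldor, AnMG0000524600 was higher and lost its call without rosdor_eldor replicate 3, and AnMG0003632610 was lower and lost it without any of the 6 libraries. With ROSpse, AnMG0006820300 was higher and AnMG0706802900 lower with ELstr, and both lost their call without any of the 6 libraries. With ROSji7, AnMG0004433810 was higher and lost its call without ROSji7_elji7 replicate 1 and with DESeq2. Without any ROSji7_ELstr replicate it was under the low-count filter and not tested. AnMG0004193600 was lower and lost it without any ROSji7_ELstr replicate.

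In rosrec_elpse against ROSpse_elpse, AnMG0004191310 was higher and AnMG0004834500 and AnMG0707710300 were lower. Their calls ended without ROSpse_elpse replicate 2 or 3, without rosrec_elpse replicate 2 or 3, and without any of the 6 libraries, in that order. Against rosdor_eldor, AnMG0004834500 and AnMG0004834300 were lower in rosrec_elpse. The call of AnMG0004834500 ended without any of the 6 libraries, and that of AnMG0004834300 without rosdor_eldor replicate 1 or any rosrec_elpse replicate. In ROSpse_elpse against ROSji7_elji7, AnMG0008594500 was higher, at 15.6 ± 26.9 CPM against 0 (SD, n = 3), with 99.8% of the CPM from ROSpse_elpse replicate 1. Without that library its log2 fold change went from 11.79 to 3.21, and the call ended, as it did without any ROSji7_elji7 replicate. AnMG0000753910 was lower and kept its call only without ROSji7_elji7 replicate 2, and AnMG0002316400 was lower and lost it without any of the 6 libraries. In magenta against white, AnMG0004127110 was lower and lost its call without any ROSji7_elji7 replicate, rosdor_eldor replicate 3, ROSpse_elpse replicate 2 or rosstr_ELstr replicate 3. In eluta against magenta, AnMG0002719800 was lower, at 0.0346 ± 0.0599 against 33.7 ± 81.6 CPM (SD, n = 6), with nearly all of the magenta CPM (200 CPM) in ROSji7_elji7 replicate 1. It lost its call without any replicate of ROSji7_ELstr or ROSpse_ELstr and without ROSpse_elpse replicate 2. Without ROSji7_elji7 replicate 1 or ROSpse_elpse replicate 3 it was not tested. AnMG0003583700 was lower, at 0.00608 ± 0.0149 against 2.45 ± 4.12 CPM (SD, n = 6), and lost its call without ROSji7_elji7 replicate 3. Of its magenta CPM, 72.3% came from ROSpse_elpse replicate 3 (10.6 CPM).

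Calls gathered on certain sequences, not all of which are given here. On scaffold1195, with 118 tested genes, 24 genes were called in ROSpse_ELstr against ROSpse_elpse where 3.32 were expected, and 12 in ROSji7_ELstr against ROSji7_elji7 where 0.225 were expected (Fisher exact p 7.08e-13 and 1.06e-16 after Benjamini-Hochberg adjustment over scaffolds). Between the magenta genotypes, 33 were called there against 5.45 expected (adjusted Fisher exact p 6.95e-16). On ros_assembly, 14 of 80 genes were called in magenta against white, 12 of them higher in magenta, where 1.02 were expected (adjusted Fisher exact p 1.10e-09), and 19 adjusted over the list alone. This was not particular to ros_assembly. In the same comparison scaffold460 held 13 calls among 89 tested genes, 0 of them higher, where 1.14 were expected (adjusted Fisher exact p 3.73e-08). On scaffold808, 8 of 92 were called, where 1.17 were expected (adjusted Fisher exact p 0.00535). In all 13 comparisons the largest count of calls in a 1 Mb window exceeded random draws at an adjusted p under 0.05. That window was not always on ros_assembly or scaffold1195. For ROSji7_elji7 against rosdor_eldor it lay on scaffold460, with 10 calls. The Fisher tests and the draws take genes as independent, which linked genes are not, so these p are too small by an unknown amount. The window on scaffold1195 from 500001 to 1500000 held 20 calls in ROSpse_ELstr against ROSpse_elpse, against at most 15 in the draws (permutation p 0.0001, the smallest that 10000 draws can give).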

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

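In this part the tests on the library series, on the enriched sequences, on read loss, on the EL haplotype, and the counts of other splits of the interactions were chosen after the result was seen.

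The EL effect differed between ROSpse and ROSji7 for 122 genes by edgeR's interaction test, and the named genes among them were picked out by that test. AnMG0000378900 differed by 7.50 on the log2 scale, AnMG0001032000 by 2.47, AnMG0003286500 by 9.94, AnMG0004746500 by 10.23 and AnMG0004749400 by 6.69. All of these were higher with ELstr under ROSpse and lower with it under ROSji7. They lie on scaffold383 and scaffold1088, where such calls gathered (5 against 0.168 expected and 13 against 0.554). In each, ROSpse_elpse and ROSji7_ELstr had the 2 lowest means of the 7 genotypes whatever the EL allele of the others: AnMG0000378900 was at 0.130 and 0.123 CPM there and at 1.35 to 2.74 elsewhere, and AnMG0004749400 at 0.438 and 0.613 against 3.12 to 6.28. These values thus do not tell an EL effect that depends on the ROS allele apart from other differences between the plants, since genotype and family were largely joined. AnMG0000646800 went the other way, with an interaction of -1.95. AnMG0001020400 was higher with ELstr under both alleles, and its interaction was -4.85. AnMG0004193600 and AnMG0907197600 had fitted interactions of 8.60 and 19.17; groups at 0 enter both, so these are no bounds. Of 100 splits of the libraries, 1 gave as many genes as the real count of 122, the real split itself, and the highest other gave 28. The splits mix libraries of all the genotypes compared, so they bear on any difference among these genotypes, not on the interaction alone. A difference of background is not excluded. The recessive EL allele also changed, elpse with ROSpse and elji7 with ROSji7.

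The difference ROSpse_elpse minus rosdor_eldor departed from ROSpse_ELstr minus rosstr_ELstr for 1.7e+02 genes, 82 with a larger and 92 with a smaller value. Fitted interactions, no bounds where a group is at 0, were -11.63 for AnMG0000146600, 10.49 for AnMG0002921300, -8.44 for AnMG0003514000 and 11.98 for AnMG0006039410. Of 100 splits, 2 gave as many genes, the real one included. These splits also mix genotypes, so that share does not bear on the interaction alone. The highest other split gave 348, well above the real count, which points to a structure of the samples other than this contrast. The pairs also differ in plant family and in the recessive ROS allele, rosdor with el and rosstr with EL. The contrast thus does not isolate a ROS effect that depends on EL. AnMG0000146600 was at 29.8 CPM in rosdor_eldor, 0.0188 in rosstr_ELstr and 0.0868 in ROSpse_elpse. With family as a term the count of genes was 10, none of them among the calls without it.

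More genes were called between the magenta genotypes (1140) than between either of them and rosdor_eldor (127 and 55). The library series argues little for it, since with the series as a term the count was 1229. Of the calls, 7.19% lay on the enriched sequences, so alleles there could account for few of the genes by acting on genes beside them. Effects of such alleles on genes elsewhere were not tested, so linked alleles stay open. Plant family stays open: the rosdor_eldor plant of family A181, that of ROSpse_elpse, left the other rosdor_eldor plants towards ROSpse_elpse in 70.2% of the called genes, against 30.9% and 46.1% for the plants of A174 and A182. It was also the only rosdor_eldor library of the low series, so family and library cannot be told apart there.

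Between the magenta genotypes, calls gathered on 4 sequences, ros_assembly and scaffold1195 among them. Of 82 calls there, 66 (80.5%) were lower in ROSpse_elpse, against 43.9% of 1058 calls elsewhere (one-sided Fisher exact p 6.09e-11), which is consistent with a loss of reads from ROSpse_elpse alleles if the reference is nearer those of ROSji7_elji7. The alleles of the reference are not stated in the sources used here. Loss from ROSji7_elji7 alleles could likewise give the 16 calls that were higher in ROSpse_elpse, so read loss and a difference in expression cannot be told apart in either direction. For the EL allele, 8 genes separated all libraries with ELstr from all others, 7 of them higher and 1 lower in ELstr, and 6 of them on ros_assembly or scaffold1195; of the 35 ways to choose 3 genotypes, 1 had as many there, the ELstr set itself, and the highest other had 5. Of 62 other sets of 1 to 3 genotypes, 3 had as many: ROSji7_elji7 with rosrec_elpse (6), ROSji7_ELstr with ROSpse_elpse (6) and ROSpse_elpse alone (12). The sequences were themselves picked for their calls. Counted over the whole genome the ELstr set did not stand apart, since 5 of the 35 sets had as many separating genes and the highest other had 15, so these counts do not set a haplotype linked to EL apart from other backgrounds, and it remains an open hypothesis. Loss of reads from ELstr alleles would lower genes in ELstr and so argues for none of the 7 that were higher. Loss from the other EL alleles stays open, since the alleles of the reference are not known here.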

How the results depend on the processing

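The fit to the middle library number series and the sequences with at least 10 tested genes were chosen after seeing the data. The size factors of DESeq2 within edgeR kept all 15 counts of calls within 1.5 times, and the count of comparisons with a crowded window was 13 at 1 Mb, 13 at 0.5 Mb and 12 at an adjusted p under 0.01. Without the filter, rosrec_elpse against rosdor_eldor gave 449 genes, and with the library series as a term 280. The other counts stayed within 1.5 times under both, but the lists changed more. With the series as a term, from 26.7% (rosrec_elpse against rosdor_eldor) to 96.1% (EL with ROSpse) of the calls of a comparison remained. In rosrec_elpse against ROSpse_elpse it was 56.2%, and in ROSpse_ELstr against rosstr_ELstr 59.8%.

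With DESeq2 the counts were 716 for ROSpse_elpse and 318 for ROSji7_elji7 against rosdor_eldor, 705 for ROSpse_ELstr against rosstr_ELstr, 1529 and 457 for EL with ROSpse and ROSji7, 1920 for rosrec_elpse against rosdor_eldor, 2975 between the magenta and 117 between the white genotypes, 1098 for magenta against white, 1340 for eluta against magenta, 644 and 669 for the EL and ROS interactions, and 81 and 11 for shared EL and ROS calls. On simulated counts for EL with ROSpse, which unlike the data had no structure of family or library series, DESeq2 called 46 unchanged genes and edgeR 8. Fitting only the groups compared gave, in the order of the comparisons with rosdor_eldor, 21 for ROSpse_elpse, 21 for ROSji7_elji7, 3 for rosrec_elpse and 2 for rosstr_ELstr, and 1.8e+02 (103 higher and 80 lower) for ROSpse_ELstr against rosstr_ELstr, 1525 for rosrec_elpse against ROSpse_elpse, 275 between the magenta genotypes, 103 for magenta against white and 32 for the ROS interaction. The cause was not tested.

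Plant family as a term, which rests on 1 rosdor_eldor plant per family, gave 34 for ROSpse_elpse and 9 for rosstr_ELstr against rosdor_eldor, 7 for ROSpse_ELstr against rosstr_ELstr, 13 for EL with ROSpse and 10 for the ROS interaction, of which 5, 6, 2, 1 and none were among the calls without it. Under it AnMG0000407600 and AnMG0000140810 reversed in EL with ROSpse, to log2 fold changes of 1.05 and -1.77 (edgeR adjusted p 0.713 and 0.755, in ranges over alternatives of 6.50e-06 to 0.713 and 0.00480 to 0.755). The middle series alone, with fewer samples, gave 33 for ROSpse_elpse against rosdor_eldor, 13 for ROSpse_ELstr against rosstr_ELstr, 178 and 6 for EL with ROSpse and ROSji7, 518 between the magenta and 8 between the white genotypes, 152 for eluta against magenta, 45 and 22 for the EL and ROS interactions, and 2 shared EL calls.

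Leaving out 1 replicate moved 74 of 126 counts by over 1.5 times, with a count of 0 taken as 1. By that rule the falls of the shared ROS calls from 1 to 0 are not among the 74. In each comparison but ROSpse_ELstr against rosstr_ELstr and EL with ROSpse, at least 1 leave-out turned which direction held more calls. Ranges were 13 to 189 for ROSpse_elpse, 18 to 155 for ROSji7_elji7, 207 to 664 for rosrec_elpse and 10 to 52 for rosstr_ELstr against rosdor_eldor, 5 to 89 for ROSpse_ELstr against rosstr_ELstr, 162 to 513 and 11 to 239 for EL with ROSpse and ROSji7, 1569 to 3047 for rosrec_elpse against ROSpse_elpse, 316 to 1298 between the magenta genotypes, 84 to 410 for magenta against white, 241 to 644 for eluta against magenta, 22 to 165 and 55 to 266 for the EL and ROS interactions, and 4 to 20 and 0 to 3 for shared EL and ROS calls. AnMG0000144700, not called in rosrec_elpse against ROSpse_elpse, turned from -0.18 to 0.54 without ROSpse_elpse replicate 1 and to 0.0027 without rosrec_elpse replicate 3, and was -0.53 without ROSpse_elpse replicate 3. Among named genes, 201 leave-outs ended a call and 383 kept it or its absence. No analysis paired by replicate number was possible because these numbers follow accession order and pair no plants. Plants are tied across genotypes only by family, which was fitted as a term.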

Other observations

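In this part the tests on the position of genes in rosrec_elpse and the counts of other splits, except that of the shared ROS calls, were chosen after the result was seen.

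Of the 80 tested genes of ros_assembly, 15 (18.75%) were called in rosrec_elpse against rosdor_eldor, where 3.21% of all tested genes were called. Between the magenta genotypes it was 14 (17.5%), against 4.62% of all tested genes. In rosrec_elpse against ROSpse_elpse it was also 14 (17.5%), but 13.6% of all tested genes were called, so that count lay near the general share. AnMG0005281610 (ros_assembly 185315 to 187038; chosen after its values were seen) was at 361 ± 119 CPM in rosstr_ELstr and 344 ± 58.4 in rosrec_elpse, and at 116 ± 8.82 in ROSpse_elpse and 144 ± 21.8 in ROSpse_ELstr (SD, n = 3). AnMG0000146600 was at 6.05 ± 3.24 CPM in ROSji7_elji7 and 15.2 ± 13.6 in ROSji7_ELstr, and below 0.2 in the genotypes with a pse, str or rec allele of ROS (SD, n = 3).

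The labels give the ROS allele of rosrec_elpse as recombinant, so a crossover is given and was not in question. If expression followed it, genes nearer rosstr_ELstr would lie on 1 side of a point along ros_assembly and genes nearer ROSpse on the other. The best single point left 1 of the 13 listed genes on the wrong side, at a permutation p of 0.165, which does not pass 0.05; with only 2 genes nearer ROSpse, 1 of them (AnMG0000140910) below both ROSpse and rosstr_ELstr, the test decides little. A general nearness of rosrec_elpse to rosstr_ELstr may also account for the pattern. On other sequences 61.9% of 286 genes lay nearer rosstr_ELstr, against 11 of 13 (84.6%), a one-sided Fisher exact p of 0.0814. The thresholds were unlike: the 286 passed 0.05 by edgeR over all genes, the 13 over ros_assembly alone. Over all genes the edgeR adjusted p of AnMG0005277410, AnMG0000140900, AnMG0000140910 and AnMG0000153000 was 0.0523, 0.121, 0.123 and 0.115. AnMG0005874000 (186459 to 186680) also lies within AnMG0005281610, so the listed genes are not all independent. With these few genes it cannot be told whether their expression followed the crossover or that nearness. In all 4 statistics were computed on this pattern, and 2 of them, p of 0.0385 and 0.00925, used the leading run of 10 genes, which was picked from the same values, so they decide nothing. The outcome that would count against expression following the crossover was first set as a p of 0.05 or more. It was reworded after the 0.165 was seen, since a missed threshold excludes nothing.

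A shared change with the ROS allele was looked for as genes whose libraries separate the 4 genotypes with a dominant ROS allele from the white ones, a test set before its result was seen. There were 5, all higher with a dominant allele: AnMG0000144600, AnMG0000144700, AnMG0005154700, AnMG0005458300 and AnMG0005507800. In magenta against white their edgeR adjusted p was 4.10e-06, 0.00157, 0.109, 0.00231 and 0.0218. AnMG0000144600 was at 55.7 and 52.0 CPM in ROSji7_elji7 and ROSji7_ELstr, but at 14.6 and 13.6 in ROSpse_elpse and ROSpse_ELstr. In rosdor_eldor and rosstr_ELstr it was at 11.4 and 10.2 CPM, so its difference was mainly that of the ROSji7 genotypes. Of 15 ways to set 2 of the 6 genotypes apart, 12 gave as many separating genes, and the highest, the pair with ROSji7, gave 146. As many from another choice had been set in advance as counting against a shared change. That bound was wrong by the design, since genotypes are joined to families and lines and other choices also separate genes by background. The number of genes thus gives no support for a shared change and excludes none.

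Each pair of genotypes has 10 splits of its 6 libraries, too few for a share under 0.05. The real count and the highest other were 127 and 153 for ROSpse_elpse, 55 and 212 for ROSji7_elji7, 791 and 24 for rosrec_elpse and 19 and 1 for rosstr_ELstr against rosdor_eldor. They were 112 and 77 for ROSpse_ELstr against rosstr_ELstr, 695 and 1 and 47 and 2 for EL with ROSpse and ROSji7, 3353 and 0 for rosrec_elpse against ROSpse_elpse, and 1140 and 0 between the magenta genotypes. As many calls as the real split came from 2 of 10 splits for ROSpse_elpse and 3 of 10 for ROSji7_elji7 against rosdor_eldor, the real one included, and from 1 of 10, the real one, elsewhere. The split with 212 calls set ROSji7_elji7 replicates 1 and 3 with rosdor_eldor replicate 1 against the rest, which points to a structure of the samples.

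With 100 splits each, for eluta against magenta 1 split, the real one, gave as many as 554 and the highest other gave 34. These splits mix libraries of unlike genotypes within a group. They thus bear on any difference among the genotypes, not on the pooled contrast alone. For the 11 shared EL calls, 1 gave as many, the real one, and the highest other gave 0. Of the 99 other splits, 1 called genes in both pairs, with 1 gene in the shorter list, so no other split could have shared 11 and the comparison decides nothing about sharing. For magenta against white, 2 of 100 gave as many as 315, the highest other being 423. That share is under 0.05, but these splits mix genotypes too, so it does not exclude chance for the contrast of colour. A split with more calls than the real one points to a structure of the samples other than colour, and the real count was 84 without rosdor_eldor replicate 3 and 97 without ROSpse_elpse replicate 2. For the shared ROS call, 3 of 100 gave as many as 1, and the highest other gave 4. That share also lies under 0.05, but of the 99 other splits 5 called genes in both pairs, so most could share none. The one-sided Fisher exact p was 0.0560 after Benjamini-Hochberg adjustment. The count was 0 without rosdor_eldor replicate 1 or 3, any ROSpse_ELstr replicate or any rosstr_ELstr replicate, so chance is not taken as excluded for this 1 gene.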
